A study of Mus musculus with 12 samples.

How the data were processed

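RNA was measured in 12 libraries of mouse rectum, in 4 groups. The control group held 3 libraries, Lgr5-Apc 4, Cdx2-Apc 3 and Lgr5-Cdx2-Apc 2. Each library carries the title of its own tissue sample. Nothing in the labels says whether any samples came from the same animal, so the p-values measure the spread between these samples and no more. The labels give RNeasy Plus extraction with DNase treatment, NEBNext Ultra II Directional libraries, and STAR, Cufflinks and Cuffdiff on the mm10 genome, without versions or the gene annotation used.

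The values deposited by the authors are FPKM (fragments scaled to transcript length and library size), 1 value per gene and library. The file header names no unit. The values were checked against it: they are decimals, their totals differ between libraries and they are highest for short RNAs. Whether the authors rescaled the libraries to one another is not stated. Depth in reads is not given and whole reads were not recovered from the values, so no counting interval or detection floor was computed and a value of 0 is given as listed at 0. The table held 27831 lines. Of these, 25 carried names that a spreadsheet had turned into dates, and they were kept unnamed. Counting date names, 46 repeated symbols stood on 94 lines. For each repeated symbol other than a date, only the line with the highest mean was kept, which left 27785 genes. Gene positions came from GENCODE M21 on GRCm38, the same build as mm10, where 95.9% of the symbols were found.

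Genes with at least 1 FPKM in at least 2 of the 12 libraries were tested, 17360 in all. The values were taken as log2(FPKM + 1) with a pseudocount of 1 FPKM and no further scaling. One linear model with a term per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along the intensity trend. There were 7 contrasts: each Apc group against control, Lgr5-Cdx2-Apc against Lgr5-Apc and against Cdx2-Apc, Lgr5-Apc against Cdx2-Apc, and the departure from additivity, which is Lgr5-Cdx2-Apc minus Lgr5-Apc minus Cdx2-Apc plus control. A gene was called when its Benjamini-Hochberg adjusted p within the contrast was below 0.05. All tests of genes were two-sided.

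The analysis also used 43 gene lists with 815 genes, for cell types, gut regions and pathways. The groups, the contrasts, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Members are counted past the threshold over all genes tested and adjusted over the list alone. The lists were tested again with a correlation estimated from the data and with fry, which asks whether the members of a list move, on balance, one way, and compares them with no other genes. Of 301 list tests, camera called 121 at the preset correlation, and 0 of them held with an estimated correlation. The median, the mean and the direction of the test differed in sign for 35 list tests, of which 0 were called.

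Genes were named by a rule. It took the 10 genes with the largest increase and the 10 with the largest decrease among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the libraries compared, and all of them where fewer passed. Overlap was not asked for the departure from additivity. Where none passed, the 3 genes with the smallest p in each direction were taken and are given as not passing. Unnamed models, small RNAs and receptor or antibody segments were skipped. The rule also took Apc, Lgr5 and Cdx2 everywhere and the 2 to 4 members with the smallest p of each list described. Of the genes the rule took, 1 is not reported here.

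The procedure was tested on simulated data with the group sizes of these libraries and 1 spread per gene in all groups. Changes were placed only in genes with a mean log2(FPKM + 1) above 2. Genes varied independently, without the shared differences in tissue composition between these libraries, so the rates below do not cover that structure. Over the 6 comparisons of groups it recovered between 92.4% and 95.5% of genes given a log2 change of 3, between 82.1% and 91% of those given 2 and between 14.9% and 40.3% of those given 1, and it called between 4 and 11 unchanged genes. Libraries with the same replicate number in different groups were no more alike than others: the 15 same-number pairs had a median excess correlation of -0.02. The replicate number was therefore left out of the model.

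The alternatives tried were other pseudocounts, no filter and a stricter one, median-of-ratios and quantile scaling, fits on the compared groups alone, library quality weights, robust moderation, a replicate block, smooth muscle and squamous scores as covariates, a minimum fold size and leaving out each library. Of these, 4 were added after seeing the data: leaving out a pair of libraries that stand apart, a columnar epithelium covariate, removal of short RNAs with equal totals, and removal of genes on chromosomes X and Y. Count-based tests were left out, since the values are not counts. Figures and permutation tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.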

Results

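Gene expression was measured by RNA sequencing in 12 libraries of mouse rectum. In the Apc groups the mice carried floxed Apc, the tumour suppressor that restrains Wnt signalling, and tamoxifen-inducible Cre recombinase. Cre was driven by Lgr5, a marker of intestinal stem cells, in the Lgr5-Apc group (n = 4), by Cdx2, a gene of hindgut epithelium, in the Cdx2-Apc group (n = 3), and by both in the Lgr5-Cdx2-Apc group (n = 2). The control samples (n = 3) are titled wild type, while their genotype field names the Cdx2 driver and floxed Apc with WT in brackets, so whether they carried Cre or floxed Apc is open. A tamoxifen protocol of 25 mg/kg on 5 days stands on every sample, but the tamoxifen characteristic is missing from the control samples, so whether they were injected is open too. Each comparison with control therefore holds genotype and possibly tamoxifen. Values are FPKM. Depth in reads is unknown. Total FPKM per library ran from 451297 in Cdx2-Apc replicate 2 to 728462 in control replicate 3, and 20522 to 22562 genes had a value above 0. Short RNAs and ribosomal RNA took 15.8% to 44.9% of the total.

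Tissue composition differed between libraries of the same group. The mean log2(FPKM + 1) of the squamous epithelium list was 9.17 and 8.39 in Lgr5-Apc replicates 2 and 3, 4.89 and 1.33 in replicates 1 and 4, 6.75 in control replicate 1 against 2.65 and 2.45 in the other controls, and 7.07 and 8.40 in the Lgr5-Cdx2-Apc libraries. The skeletal muscle score was 4.40 and 4.75 in the Lgr5-Cdx2-Apc libraries, 4.68 in Lgr5-Apc replicate 2 and at most 2.02 in the other 9 libraries. The smooth muscle score was 2.92 and 2.72 in the Lgr5-Cdx2-Apc libraries and 4.65 to 6.69 elsewhere. The first principal component held 53.8% of the variance and set the Lgr5-Cdx2-Apc libraries, at 93.1 and 132, and Lgr5-Apc replicate 2, at 99.8, apart. Lgr5-Apc replicate 3, at 31.2, and control replicate 1, at -4.34, lay between these and the remaining libraries, at -31.9 or lower.

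**Figure D1:**
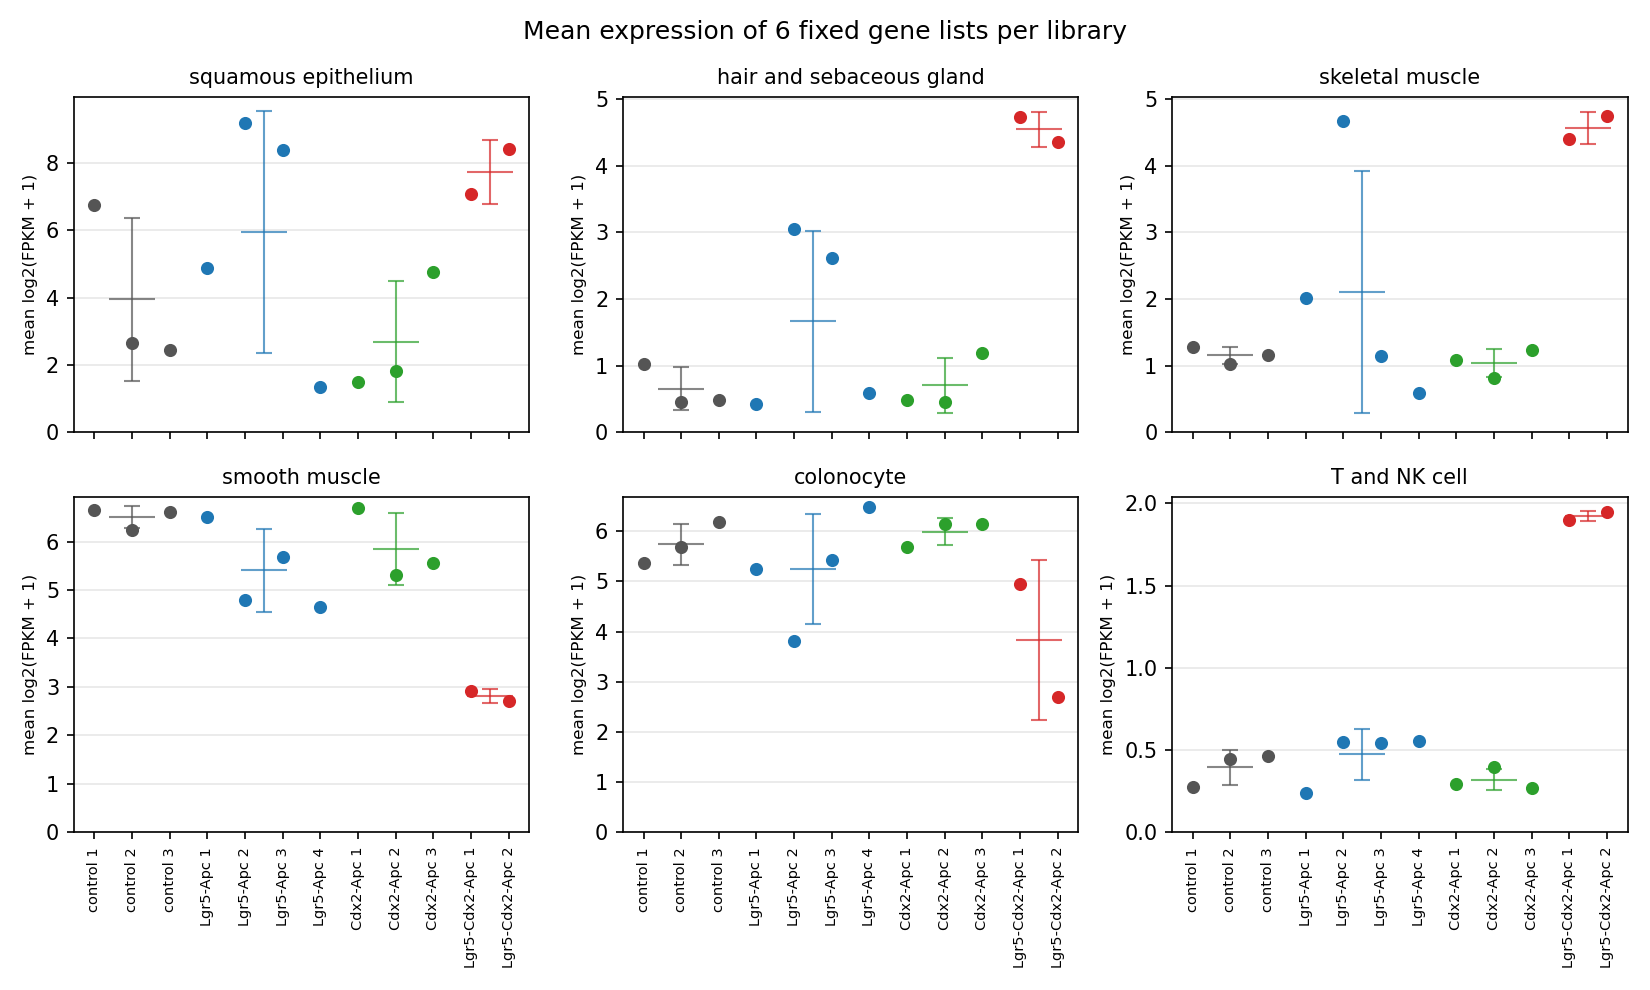
Mean log2(FPKM + 1) of 6 gene lists in each of the 12 libraries, coloured by group; points are libraries, long bars are group means and whiskers are 1 SD. Both Lgr5-Cdx2-Apc libraries lie lowest for smooth muscle, at 2.92 and 2.72, while Lgr5-Apc replicate 2 lies highest for squamous epithelium, at 9.17.

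The recombined gene and the driver genes did not pass the test in any comparison. Apc (ENSMUSG00000005871.15, chromosome 18, 34220924 to 34322552 on GRCm38) was 13.5 to 18.8 FPKM in all libraries, with means of 17.1 ± 1.55 in control (SD, n = 3), 15.6 ± 2.05 in Lgr5-Apc (SD, n = 4), 16.7 ± 1.21 in Cdx2-Apc (SD, n = 3) and 14.2 ± 1.08 in Lgr5-Cdx2-Apc (SD, n = 2). A value per gene does not show whether floxed exons were removed. Lgr5 (ENSMUSG00000020140.15, chromosome 10, 115450311 to 115587780) ran from 1.30 to 5.95 FPKM. Cdx2 (ENSMUSG00000029646.3, chromosome 5, 147300805 to 147307270) ran from 0.248 to 151 FPKM, and the highest value was in Lgr5-Apc replicate 4.

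The first comparison asked what changes with the Lgr5 driver. Against control, Lgr5-Apc rectum had 0 genes higher and 2 lower of 17360 tested (limma, Benjamini-Hochberg adjusted p below 0.05; 1881 genes at an unadjusted p under 0.05). The 2 called genes fall outside the naming rule and were chosen after their values were seen. Ighv1-85, an antibody heavy chain segment, was 3.32, 4.28 and 4.94 FPKM in the controls and listed at 0 in Lgr5-Apc. Snora61, a small nucleolar RNA, was 209, 21.9 and 244 FPKM in the controls and listed at 0 in the other 9 libraries. Among genes that did not pass, Eno1b, a copy of the glycolytic enolase gene, had a log2 difference of -3.68 ± 0.54 (SE; adjusted p = 0.24), from 13 ± 3.14 FPKM in control (SD, n = 3) to 0.0731 ± 0.0622 in Lgr5-Apc (SD, n = 4). Differences for Aif1, a macrophage gene, at -0.99, and Cyp2d9, a cytochrome P450, at -1.82 did not pass either. The same holds for Samd1 at 0.93, Sema7a, a semaphorin, at 0.90 and Rps4l at 1.16 (adjusted p = 0.36 for each).

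As a list, smooth muscle genes lay lower in Lgr5-Apc, with a median log2 difference of -1.13 (camera adjusted p = 2.85e-09; adjusted p = 0.885 with an estimated correlation). None of its 20 members passed over all genes or adjusted over the list alone, with 11 at an unadjusted p under 0.05. Its leading members were Synm, an intermediate filament protein, at -1.78 ± 0.55 and Flnc, a muscle filamin, at -1.36 ± 0.48 (SE). The squamous list had a median of 2.02 (camera adjusted p = 0.00626; adjusted p = 0.885 with an estimated correlation) and 0 of 28 members called, with 1 at an unadjusted p under 0.05. The squamous score was 4.89, 9.17, 8.39 and 1.33 in Lgr5-Apc replicates 1, 2, 3 and 4. It was 6.75, 2.65 and 2.45 in control replicates 1, 2 and 3, so the groups overlapped and single libraries weighed heavily. Within Lgr5-Apc, Sprr1a, a cornified envelope protein, was 426 ± 397 FPKM and Lor, the envelope protein loricrin, 340 ± 417 (SD, n = 4). Wnt target genes were not called as a list, with a median log2 difference of 0.05 (camera adjusted p = 0.958). Of its 20 members, 0 were called and 0 were at an unadjusted p under 0.05. The count of 2 genes was 32 without control replicate 1, 4 without control replicate 3, Lgr5-Apc replicate 3 or Cdx2-Apc replicate 1, and 1 without Lgr5-Apc replicate 1.

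The comparison of Cdx2-Apc with control asked what changes with the Cdx2 driver, and the genes that passed were almost all sex-linked. Xist (chromosome X, 103460366 to 103483254), the RNA that silences an X chromosome in female cells, fell by 5.96 ± 0.34 on the log2 scale (SE; adjusted p = 8.05e-05), from 120 ± 29.8 FPKM in control (SD, n = 3) to 0.905 ± 0.209 in Cdx2-Apc (SD, n = 3). The Y genes Eif2s3y, Ddx3y, Uty and Kdm5d rose by 3.94, 3.39, 3.17 and 2.77. Eif2s3y (chromosome Y, 1010543 to 1028847), a translation initiation factor gene, went from 1.13 ± 1.67 FPKM (SD, n = 3) to 26.1 ± 2.07 (SD, n = 3; adjusted p = 0.00462). In all, 5 genes were higher and 2 lower by limma, with 285 genes at an unadjusted p under 0.05. Outside the naming rule, the other called genes were the Y gene model Gm28588, higher by 1.74, and Snora61, which was listed at 0 in Cdx2-Apc, and 6 of the 7 lie on chromosomes X or Y. The labels do not give the sex of the mice.

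**Figure D2:**
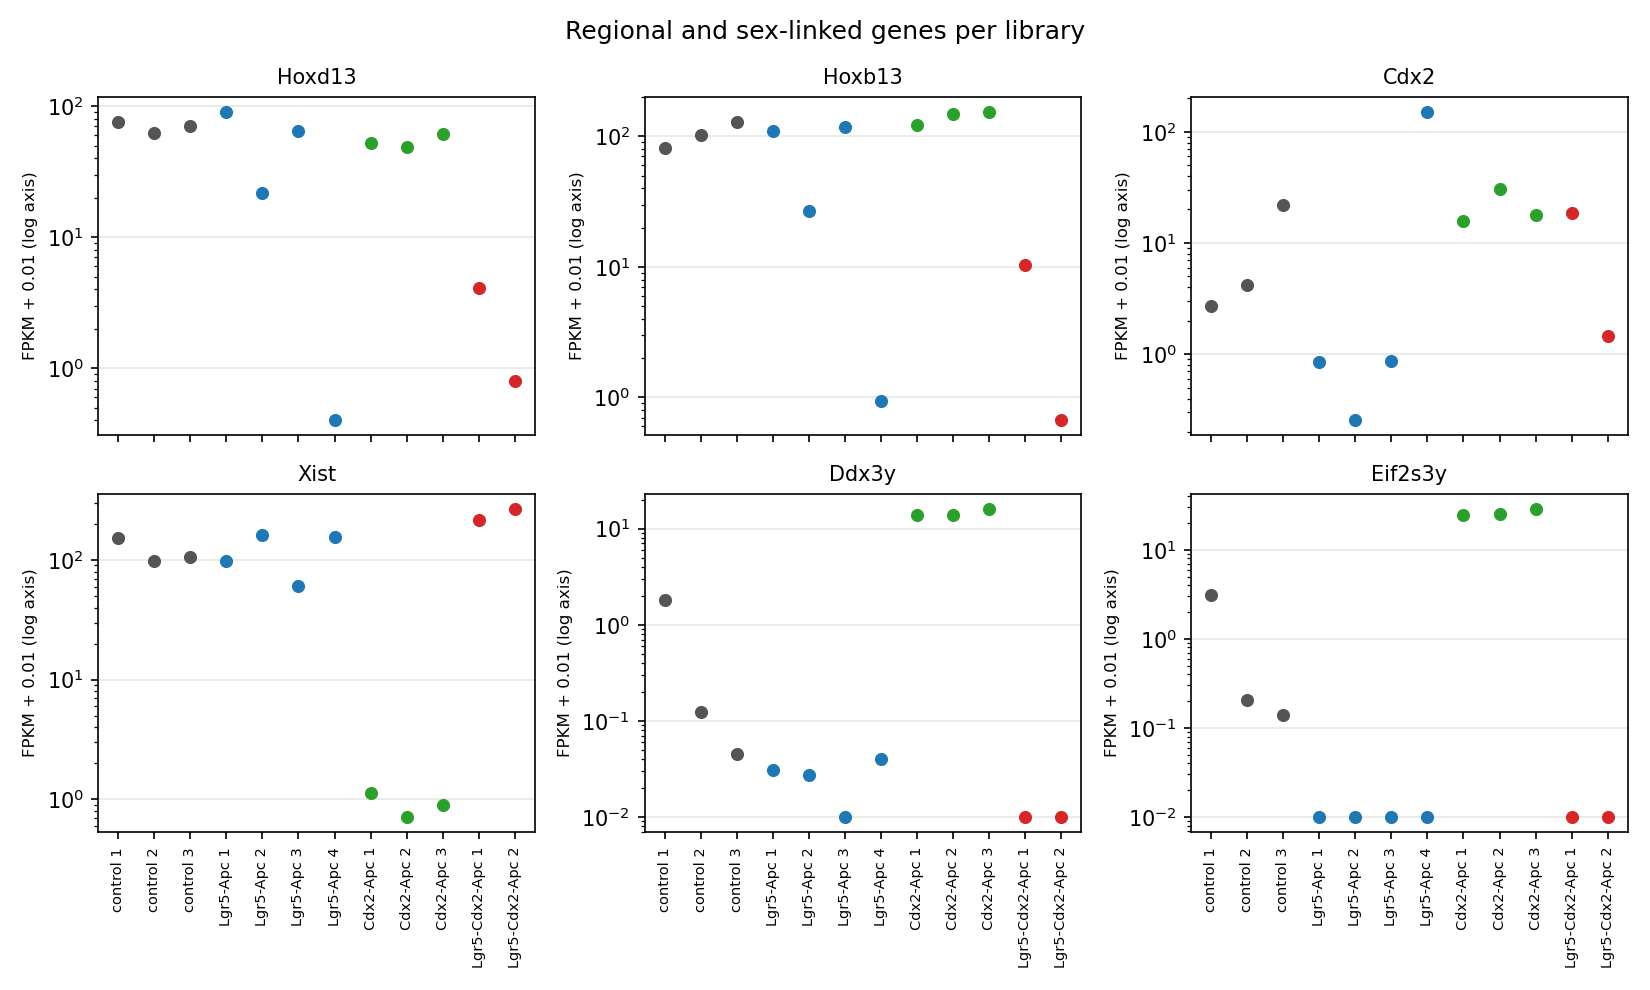
FPKM of 6 genes in each of the 12 libraries on a log axis after adding 0.01, coloured by group. Xist is 0.702 to 1.12 FPKM in the Cdx2-Apc libraries and 61.1 to 266 in the others, and Hoxd13 is lowest in Lgr5-Apc replicate 4, at 0.395.

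Of 5 sex-linked genes 4 rose and 1 fell in Cdx2-Apc, over all genes and adjusted over the list alone (camera adjusted p = 1.97e-13; adjusted p = 0.166 with an estimated correlation). Interferon response genes had a median log2 difference of 0.31 (camera adjusted p = 0.000102) and oxidative phosphorylation genes of 0.28 (camera adjusted p = 2.92e-07), each with adjusted p = 0.961 with an estimated correlation. None of the 23 and 24 members passed over all genes or adjusted over the list alone. Of the interferon members 1 was at an unadjusted p under 0.05, and of the oxidative phosphorylation members 0. In each list 1 library weighed heavily. The interferon score was 2.81, 2.25 and 2.37 in Cdx2-Apc replicates 1, 2 and 3, against 1.93 to 2.31 in control. The oxidative phosphorylation score was 6.87, 7.08 and 7.45 in control replicates 1, 2 and 3, against 7.27 to 7.46 in Cdx2-Apc. The leading members were Psmb9, an immunoproteasome subunit, at 0.74 ± 0.28, Rsad2, the antiviral protein viperin, at 0.63 ± 0.34, and the respiratory complex I subunits Ndufb8 at 0.38 ± 0.19 and Ndufs1 at 0.27 ± 0.17 (SE). The squamous list lay lower, at -1.23 (camera adjusted p = 0.000227; adjusted p = 0.961 with an estimated correlation), with 0 of 28 members called and 0 at an unadjusted p under 0.05. Its score was 6.751, 2.652 and 2.445 in control replicates 1, 2 and 3, against 1.503, 1.81 and 4.761 in Cdx2-Apc replicates 1, 2 and 3. The groups overlapped, with Cdx2-Apc replicate 3 above control replicates 2 and 3, and control replicate 1 weighed heavily in the difference. Smooth muscle genes lay at a median of -0.61 (camera adjusted p = 9.71e-10; adjusted p = 0.961 with an estimated correlation), with 0 of 20 members called and 0 at an unadjusted p under 0.05. Wnt target genes were not called as a list in Cdx2-Apc either, with a median log2 difference of 0.03 (camera adjusted p = 0.794). Of its 20 members, 0 were called and 0 were at an unadjusted p under 0.05. Without control replicate 1, the count of 7 genes was 22.

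Rectum with both drivers differed from control in skin, muscle and gut genes at once. Among the largest increases were genes of the cornifying epidermis. Krt2 (chromosome 15, 101810689 to 101818169), a keratin of the upper epidermis, rose by 9.94 ± 1.47 on the log2 scale (SE; adjusted p = 0.00326), to 1417 ± 1098 FPKM (SD, n = 2). The late cornified envelope genes Lce1a1, Lce1a2, Lce1m, Lce1b, Lce1c and Lce1d rose by 8.74, 8.44, 8.36, 8.26, 8.22 and 7.87, and Lce1l was 290 ± 48.1 FPKM (SD, n = 2) and listed at 0 in control. Lor rose by 8.16 and Krt77, a keratin of sweat gland ducts, by 7.34. The largest decreases were in smooth muscle: Actg2 (chromosome 6, 83512905 to 83536265), the enteric smooth muscle actin, fell by 6.92 ± 0.69 (SE; adjusted p = 0.000488), from 795 ± 110 FPKM in control (SD, n = 3) to 5.96 ± 3.35 (SD, n = 2). Myosin Myh11, Tagln, calponin Cnn1, Acta2 and Myl9 of the contractile apparatus were lower, at -6.32, -6.31, -6.27, -6.22 and -5.82. Gut genes followed, with Mptx1, a mucosal pentraxin, at -5.46, Sycn, or syncollin, at -5.37, Sval1 at -5.14 and B3gnt7, a glycosyltransferase, at -5.09. In all, limma called 1830 genes higher and 1485 lower of 17360. With a pseudocount of 0.1 FPKM the balance turned to 1438 and 1564, and with a mean of at least 5 FPKM to 779 and 1146. Short RNA removal with equal totals gave 2435 and 1230.

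**Figure D3:**
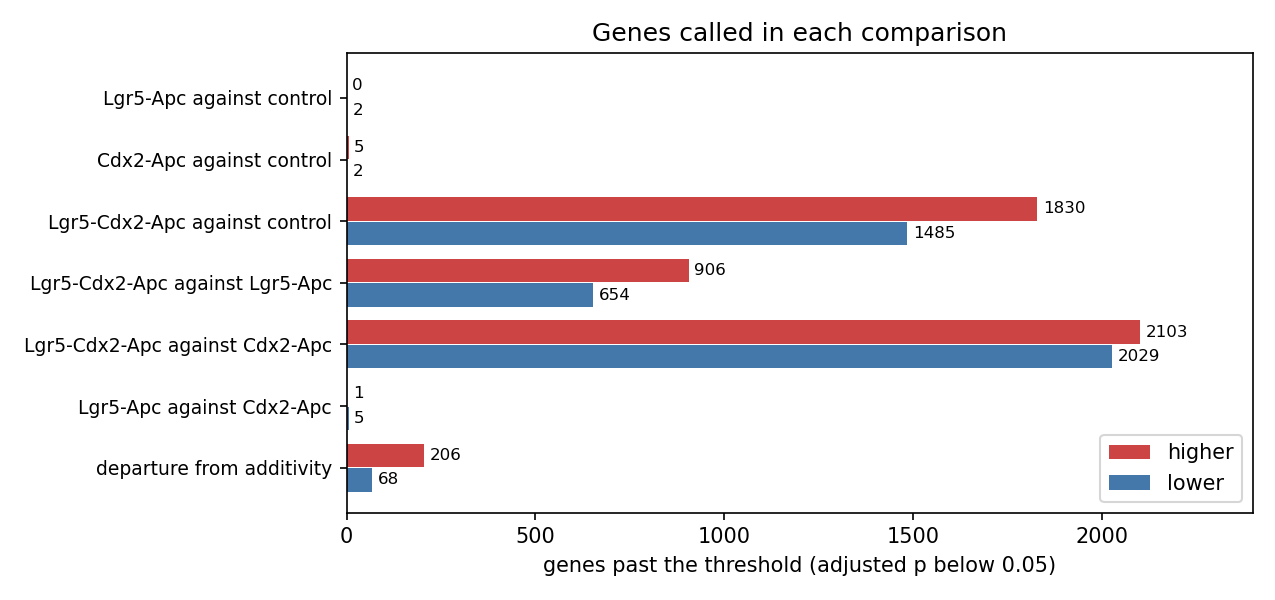
Number of genes past the threshold (limma, Benjamini-Hochberg adjusted p below 0.05) in each of the 7 comparisons; bars start at 0, with higher genes in red and lower genes in blue. The 3 comparisons of Lgr5-Cdx2-Apc with another group hold 3315, 1560 and 4132 genes, and the other 3 comparisons of groups hold 2, 7 and 6.

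By list, 12 of 15 hair and sebaceous gland genes rose against control, and 15 adjusted over the list alone (camera adjusted p = 7.81e-09). The inner root sheath keratins Krt71 and Krt25 rose by 4.92 and 3.49, and Krt27 was 12.3 ± 7.89 FPKM (SD, n = 2) and listed at 0 in control. Of the 18 skeletal muscle genes, 13 rose, and 16 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.29e-06): Atp2a1, the fast-fibre calcium pump, by 5.50, myoglobin Mb by 5.41 and troponin Tnnc2 by 4.88. In the smooth muscle list 17 of 20 fell, and 18 adjusted over the list alone (camera adjusted p = 2.01e-13). These calls were lost with adjusted p = 0.629 with an estimated correlation for each of the hair, skeletal muscle and smooth muscle lists. Of 28 squamous genes 2 rose, Lor and involucrin Ivl by 4.19, and 0 passed adjusted over the list alone (camera adjusted p = 0.00503; adjusted p = 0.836 with an estimated correlation). Sbsn, a suprabasal keratinocyte gene, had a difference of 7.40 that did not pass (adjusted p = 0.0528).

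Colonocyte, goblet cell, enteroendocrine and posterior gut lists were called lower. Columnar epithelium markers were low with them. Their score, chosen after seeing the data, averages Krt8, Krt18, Krt19, Epcam, Cdh17, Lgals4, Vil1 and Cdx1. It was 6.33 and 3.84 in Lgr5-Cdx2-Apc against 8.04 to 8.71 in control. Its member Epcam, an epithelial adhesion gene, was 175 and 65.4 FPKM against 415 to 709. Cdx1 also stands in the posterior gut list, so the score is not independent of that list. The intestinal stem cell list (camera adjusted p = 0.685, with 1 of 15 members lower) and the small intestine list (camera adjusted p = 0.944, with 2 of 20 higher and 1 lower) were not called. The counts of members in these last lists were the same adjusted over the list alone. Of 31 colonocyte genes 10 fell, and 14 adjusted over the list alone (camera adjusted p = 3.78e-06; adjusted p = 0.629 with an estimated correlation). The anion transporters Slc26a2 and Slc26a3 were at -2.33 and -4.31 and Plac8 at -4.25. Of 21 goblet cell genes 5 fell, and 8 adjusted over the list alone (camera adjusted p = 0.000312; adjusted p = 0.71 with an estimated correlation). The sialyltransferase St6galnac6 was at -3.43, trefoil factor Tff3 at -3.76 and the transcription factor Creb3l1 at -2.48. Of 17 enteroendocrine genes 3 fell, over all genes and adjusted over the list alone, the hormone Insl5 at -4.24, secretogranin Scg2 at -2.60 and secretagogin Scgn at -1.65 (camera adjusted p = 0.00572; adjusted p = 0.629 with an estimated correlation). Of 16 posterior gut genes 9 fell, and 11 adjusted over the list alone (camera adjusted p = 2.29e-05; adjusted p = 0.629 with an estimated correlation). The positional gene Hoxd10 was at -2.68, Sycn at -5.37 and the hindgut transcription factor Cdx1 at -3.33. Of 21 junction genes 10 fell and 1 rose, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000651; adjusted p = 0.629 with an estimated correlation). Occludin Ocln was at -1.58, plakophilin Pkp2 at -2.18 and F11r at -1.15. Outside the epithelium, of 17 enteric neuron genes 6 fell, and 13 adjusted over the list alone (camera adjusted p = 3.78e-06; adjusted p = 0.629 with an estimated correlation). The neuropeptide Vip was at -3.36, Hand2 at -2.60 and the synaptic protein Snap25 at -2.66.

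The lists for T and NK cells, MHC class II and chemokines were called higher with both drivers. The lists for B and plasma cells, interferon response, macrophages and dendritic cells, and neutrophils were not called (camera adjusted p = 0.867, 0.729, 0.105 and 0.33). Of 13 T and NK cell genes 10 rose, and 11 adjusted over the list alone (camera adjusted p = 7.81e-09; adjusted p = 0.162 with an estimated correlation). Trdc (chromosome 14, 54142851 to 54148868), the constant segment of the delta chain of the T cell receptor, rose by 2.28 ± 0.17 (SE; adjusted p = 0.00029), from 0.0308 ± 0.0275 FPKM in control (SD, n = 3) to 4.05 ± 0.792 (SD, n = 2), and the receptor subunits Cd3e and Cd3g rose by 3.17 and 2.95. Of 8 MHC class II genes 5 rose, and 8 adjusted over the list alone (camera adjusted p = 9.82e-05; adjusted p = 0.629 with an estimated correlation): the regulator Ciita by 1.76 and the peptide loading genes H2-DMa and H2-DMb1 by 2.35 and 2.07. Of 11 chemokine and cytokine genes 7 rose and 1 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0493; adjusted p = 0.629 with an estimated correlation): Tnf rose by 1.41 and the neutrophil attractant Cxcl2 by 1.33, and Ccl28, a chemokine of mucosal epithelium, fell by 3.31. Of 13 tuft cell genes 5 rose, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.629 with an estimated correlation): the lipoxygenase Alox5 by 2.35, the cyclooxygenase Ptgs1 by 2.51 and the transcription factor Pou2f3, which keratinocytes also express, by 5.41.

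Wnt target genes were not called as a list against control (camera adjusted p = 0.101; adjusted p = 0.629 with an estimated correlation), but 6 of 20 rose and 1 fell, or 7 and 2 adjusted over the list alone. The receptors Lgr6 and Tnfrsf19, both also known from hair follicles, rose by 4.08 and 3.94, and the transcription factor Tcf7 by 1.23. Of 24 proliferation genes 9 fell, and 1 rose and 14 fell adjusted over the list alone (camera adjusted p = 0.000509; adjusted p = 0.68 with an estimated correlation): cyclin Ccnb2 was at -1.40, Ube2c at -1.38 and survivin Birc5 at -1.06. Of 24 oxidative phosphorylation genes 17 fell, and 21 adjusted over the list alone (camera adjusted p = 4.12e-09; adjusted p = 0.629 with an estimated correlation). The ATP synthase subunit Atp5c1 was at -0.85 and Uqcrc2 of complex III at -1.17. All of these shifts stood beside the low smooth muscle scores of 2.92 and 2.72, the high squamous scores of 7.07 and 8.40 and low columnar epithelium scores. The count of 3315 genes was 1225 without control replicate 2, 995 without control replicate 3, 1046 without Lgr5-Cdx2-Apc replicate 1 and 428 without replicate 2, and 19 of the 67 named genes called were called in all 12 fits that left out 1 library. With the smooth muscle score in the model limma called 0 genes (1390 at an unadjusted p under 0.05), with the squamous score 1492 and with the columnar epithelium score, added after seeing the data, 64. The smooth muscle score was 4.65 to 6.69 in the other groups, apart from both Lgr5-Cdx2-Apc libraries. That fit therefore cannot tell a group difference from muscle content, and calls were likely to be lost whatever the cause.

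Lgr5-Cdx2-Apc against Lgr5-Apc asked what the Cdx2 driver adds to the Lgr5 driver. Among the largest increases were again genes of skin and hair, but the squamous list was not called (camera adjusted p = 0.123), with 0 of 28 members past the threshold by limma, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Lgr5-Apc replicates 2 and 3 had squamous scores of 9.17 and 8.39. Krt2 rose by 8.46 ± 1.39 (SE; adjusted p = 0.00679), from 15.9 ± 31.2 FPKM (SD, n = 4) to 1417 ± 1098 (SD, n = 2). Clca3a2, a chloride channel regulator, rose by 5.25, the serpin Serpina3b by 5.25, Skint9 and Skint5, which keratinocytes and thymic epithelium express, by 5.07 and 5.02, Cyp2b19, a keratinocyte cytochrome P450, by 4.88, the hair genes Krtap7-1 and Krt71 by 4.74 and 4.70, Mill1 by 4.34 and the sulfotransferase Sult5a1 by 4.28. Actg2 fell by 5.67 ± 0.65 (SE; adjusted p = 0.00124), and Acta2, Myh11, Tagln, Cnn1, Myl9 and the kinase Mylk of smooth muscle were lower, at -4.91, -4.90, -4.80, -4.79, -4.75 and -3.65. Pglyrp1, which binds bacterial cell walls, was at -3.89, the neutrophil surface protein Cd177 at -3.69 and Hsd11b2, which inactivates corticosterone, at -3.63. In all, limma called 906 genes higher and 654 lower. This balance turned to 466 and 650 with a pseudocount of 0.1 FPKM and to 115 and 387 with a mean of at least 5 FPKM. Short RNA removal with equal totals gave 1247 and 386.

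All 8 MHC class II genes rose against Lgr5-Apc, over all genes and adjusted over the list alone (camera adjusted p = 4e-07; adjusted p = 0.428 with an estimated correlation). Ciita was at 1.82, H2-DMa at 2.40 and H2-DMb1 at 2.13. Of 13 T and NK cell genes 10 rose, and 11 adjusted over the list alone (camera adjusted p = 1.79e-10; adjusted p = 0.0892 with an estimated correlation). Trdc was at 2.14, Cd3e at 2.84 and the cytotoxic granule protein Nkg7 at 2.80. Of 17 macrophage and dendritic cell genes 5 rose, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00015; adjusted p = 0.612 with an estimated correlation). Aif1 was at 1.17, the lectin Cd209a at 1.19 and the integrin Itgax went from 0.890 ± 0.460 FPKM (SD, n = 4) to 4.21 ± 0.135 (SD, n = 2). Of 15 hair genes 7 rose, and 12 adjusted over the list alone (camera adjusted p = 2.18e-08; adjusted p = 0.428 with an estimated correlation). Krt27 was at 3.52, Krt71 at 4.70 and Krt25 at 3.43. Of 20 Wnt targets 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0375; adjusted p = 0.428 with an estimated correlation). Lgr6 was at 3.46, Tnfrsf19 at 3.34 and Tcf7 at 1.09.

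Smooth muscle genes fell against Lgr5-Apc in 11 of 20 cases, and in 15 adjusted over the list alone (camera adjusted p = 1.79e-10; adjusted p = 0.428 with an estimated correlation). Of 20 glycolysis and hypoxia genes 4 fell, and 12 adjusted over the list alone (camera adjusted p = 3.65e-05; adjusted p = 0.428 with an estimated correlation). Phosphofructokinase Pfkl was at -1.30, adrenomedullin Adm at -1.14 and lactate dehydrogenase Ldha at -0.92. Of 24 oxidative phosphorylation genes 7 fell, and 20 adjusted over the list alone (camera adjusted p = 2.16e-09; adjusted p = 0.442 with an estimated correlation). Atp5c1 was at -0.77 and Ndufv1 at -0.71. Of 21 goblet cell genes 2 fell, and 4 adjusted over the list alone (camera adjusted p = 0.000142; adjusted p = 0.666 with an estimated correlation), St6galnac6 at -3.30 and Creb3l1 at -2.43, while Bcas1 at -2.20 did not pass (adjusted p = 0.0619). Of 21 junction genes 4 fell, and 14 adjusted over the list alone (camera adjusted p = 7.58e-06; adjusted p = 0.428 with an estimated correlation). F11r was at -1.13, Pkp2 at -1.89 and Ocln at -1.24. The count of 1560 genes was 697 without Lgr5-Apc replicate 1, 4463 without replicate 2, 551 without replicate 3, 919 without Cdx2-Apc replicate 2, 835 without replicate 3, 591 without Lgr5-Cdx2-Apc replicate 1 and 284 without replicate 2, and 15 of the 45 named genes called were called in all 12 such fits. It was 2 with the smooth muscle score in the model, 83 with the columnar epithelium score and 162 in a fit on these groups alone. The smooth muscle score sets the Lgr5-Cdx2-Apc libraries apart, so that fit cannot tell group from muscle content.

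Lgr5-Cdx2-Apc against Cdx2-Apc asked what the Lgr5 driver adds to the Cdx2 driver, and these groups also differ in sex-linked genes. Krt2 rose by 10.01 ± 1.47 (SE; adjusted p = 0.00292), from 0.164 ± 0.221 FPKM (SD, n = 3) to 1417 ± 1098 (SD, n = 2). The defensin gene Defb6 rose by 8.62, Lce1a1 by 8.46, Lor by 8.43, Lce1c by 8.34, Lce1b by 8.10, Lce1a2 by 7.98, the cornification gene Crct1 by 7.97, Lce1d by 7.95 and the epidermal protease Asprv1 by 7.81. The largest decreases were Mptx1 at -6.43, Actg2 at -6.40, Cnn1 at -5.82, Sycn at -5.73, Tagln at -5.70, Acta2 at -5.49, Myh11 at -5.48, B3gnt7 at -5.47, Sval1 at -5.46 and the secretory lineage lectin Reg4 at -5.39. In all, limma called 2103 genes higher and 2029 lower, and 121 of them lie on chromosomes X or Y. A pseudocount of 0.1 FPKM turned the balance to 1663 and 2109, and a mean of at least 5 FPKM to 992 and 1702. Short RNA removal with equal totals gave 2680 and 1748.

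Against Cdx2-Apc, 16 of 18 skeletal muscle genes rose and 1 fell, or 17 and 1 adjusted over the list alone (camera adjusted p = 4.88e-06). Skeletal actin Acta1 was at 6.26, Tnnc2 at 5.22 and Mb at 5.41. Of 15 hair genes 12 rose, and 14 adjusted over the list alone (camera adjusted p = 1.02e-08). Krt27 was at 3.54, Krt71 at 4.78 and Krt25 at 3.38. Both calls were lost with adjusted p = 0.59 with an estimated correlation. Of 28 squamous genes 6 rose, and 19 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000116; adjusted p = 0.656 with an estimated correlation). Lor was at 8.43, Ivl at 4.51 and the keratinocyte serpin Serpinb5 at 2.96. Of 13 T and NK cell genes 11 rose, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.27e-09; adjusted p = 0.154 with an estimated correlation). Trdc was at 2.30, Cd3e at 3.11 and Cd3g at 3.32. Of 20 Wnt targets 7 rose and 1 fell, or 7 and 2 adjusted over the list alone, without a call for the list (camera adjusted p = 0.0942). Tnfrsf19 was at 4.38, Lgr6 at 4.04 and the receptor Ephb2 at -2.25.

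Oxidative phosphorylation genes fell against Cdx2-Apc in 22 of 24 cases, and in 23 adjusted over the list alone (camera adjusted p = 5.71e-11; adjusted p = 0.59 with an estimated correlation). Ndufb8 was at -1.18 and Sdha of complex II at -1.40. Of 20 smooth muscle genes 15 fell, and 17 adjusted over the list alone (camera adjusted p = 3.45e-09; adjusted p = 0.59 with an estimated correlation). Of 31 colonocyte genes 12 fell, and 18 adjusted over the list alone (camera adjusted p = 5.71e-06; adjusted p = 0.59 with an estimated correlation). Slc26a2 was at -2.62, Slc26a3 at -4.69 and Plac8 at -4.31. Of 21 goblet cell genes 7 fell, and 10 adjusted over the list alone (camera adjusted p = 0.000174; adjusted p = 0.645 with an estimated correlation). St6galnac6 was at -4.03, Creb3l1 at -3.05 and Tff3 at -3.91. The count of 4132 genes was 2423, 1553 and 2106 without Cdx2-Apc replicates 1, 2 and 3, 1544 without Lgr5-Cdx2-Apc replicate 1 and 506 without replicate 2, and 13 of the 43 named genes called were called in all 12 such fits. With the smooth muscle score in the model limma called 0 genes (1944 at an unadjusted p under 0.05), with the squamous score 789 and with the columnar epithelium score 61. Here too, the smooth muscle score sets the Lgr5-Cdx2-Apc libraries apart, so that fit cannot tell group from muscle content.

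Lgr5-Apc against Cdx2-Apc compared the drivers with each other. All 6 genes called by limma lie on chromosomes X or Y, with 1 higher and 5 lower and 1800 genes at an unadjusted p under 0.05. Xist was higher by 5.88 ± 0.32 (SE; adjusted p = 4.7e-05), at 119 ± 48.7 FPKM (SD, n = 4) against 0.905 ± 0.209 (SD, n = 3). Ddx3y and Uty were lower by -3.94 and -3.68, and Eif2s3y and Kdm5d were listed at 0 in Lgr5-Apc, against 26.1 ± 2.07 and 7.88 ± 0.446 FPKM in Cdx2-Apc (SD, n = 3). Outside the naming rule, the remaining called gene was the Y model Gm28588. The squamous list had a median difference of 3.61 (camera adjusted p = 2.3e-07; adjusted p = 0.803 with an estimated correlation) with 0 of 28 members called and 5 at an unadjusted p under 0.05, where Sprr1a was at 5.00 ± 1.52 and Lor at 4.82 ± 1.93 (SE). Interferon response genes had a median of -0.71 (camera adjusted p = 4.63e-06; adjusted p = 0.803 with an estimated correlation) with 0 of 23 called and 7 at an unadjusted p under 0.05, where the guanylate-binding protein Gbp7 was at -0.84 ± 0.24 and Ifit2, an interferon-induced protein, at -0.76 ± 0.24 (SE). None of these members passed adjusted over the list alone. The count of 6 genes was 10 without control replicate 1, 14 without Lgr5-Apc replicate 1 and 10 without Lgr5-Apc replicate 4.

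The departure from additivity asked where both drivers together differed from the sum of the single driver effects on the log2 scale, and limma called 206 genes above it and 68 below. Whether the controls were injected is open, and a tamoxifen effect missing from them would not cancel in this contrast. Nor would a difference in sex between Cdx2-Apc and the other groups. A called gene therefore need not reflect an interaction of the drivers. Xist stood highest, at 7.06 ± 0.49 (SE; adjusted p = 0.000375), a gene whose value in Cdx2-Apc was 0.905 FPKM. Hair follicle genes followed: Krt71 at 4.56, Krtap19-4 at 4.03, Tchh at 3.95, Krtap6-5 at 3.92, Krtap15 at 3.89 and Krtap19-2 at 3.71, with the keratin Krt24 at 4.00, the interleukin receptor Il12rb2 at 4.04 and the MHC class I type gene H2-M2 at 3.63. Krtap19-2 was listed at 0 in the other 3 groups. Below the sum were Actg2 at -5.15, Cnn1 at -4.34, Myl9 at -4.23 and Acta2 at -4.19 of smooth muscle, the Y genes Eif2s3y at -3.94 and Ddx3y at -3.42, and Cd177 at -3.80, carbonic anhydrase Car2 at -3.58, the glutathione peroxidase Gpx2 at -3.38 and Ceacam10 at -3.28.

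For T and NK cells, 7 of 13 genes stood above the sum, and 11 adjusted over the list alone (camera adjusted p = 2.45e-11; adjusted p = 0.0664 with an estimated correlation). Trdc was at 2.16, Cd3g at 3.27 and Nkg7 at 3.04. Of 15 hair genes 4 stood above it, and 7 adjusted over the list alone (camera adjusted p = 6.82e-08; adjusted p = 0.458 with an estimated correlation), with Krt71, Krt27 at 3.46 and Krt25 at 3.32. Of 8 MHC class II genes 2 stood above it, and 8 adjusted over the list alone (camera adjusted p = 2.42e-06; adjusted p = 0.458 with an estimated correlation), H2-DMa at 2.43 and Ciita at 1.59, while H2-DMb1 at 1.85 did not pass (adjusted p = 0.102). The count of 274 genes was 86 without control replicate 2, 142, 2386 and 132 without Lgr5-Apc replicates 1, 2 and 3, 98, 67 and 69 without Cdx2-Apc replicates 1, 2 and 3, and 171 and 148 without Lgr5-Cdx2-Apc replicates 1 and 2. It was 9 with a pseudocount of 0.1 FPKM and 3 with the smooth muscle score in the model. That score sets the Lgr5-Cdx2-Apc libraries apart, so the fit with it cannot tell group from muscle content. The balance also turned, to 1129 above and 1257 below without Lgr5-Apc replicate 2, and to 1012 and 1180 with library quality weights.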

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

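The tests of the squamous score in other libraries, of the relation over 31 Hox genes, of the ratios among Lgr5-Apc libraries, of the shares of Y gene RNA and of Y genes and Xist in Lgr5-Cdx2-Apc were chosen after their results were seen. The other tests were written down first.

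In the Lgr5-Apc group, 4 values lay farther from the other libraries than Dixon's limit allows, of 49 measures tested (8.16%, where chance gives about 5%). In replicate 4, Lgr5 was 4.72 FPKM against 1.30 to 1.75 in the others, Cdx2 was 151 FPKM against 0.248 to 0.858, and the mesenchymal transition score was 2.17 against 3.03 to 3.16. The Lgr5 value of replicate 4 lay within the control range of 3.60 to 5.95 FPKM. Replicates 1, 2 and 3 lay below every library of the other groups, where Lgr5 was at least 2.81 and Cdx2 at least 1.44 FPKM. For Cdx2, replicate 4 was also the highest of all libraries. In replicate 1, the T and NK cell score was 0.242 against 0.542 to 0.558. It lay close to the 0.275 of control replicate 1 and the 0.271 of Cdx2-Apc replicate 3.

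The difference of Lgr5-Cdx2-Apc from control departed from the sum of those of the single-driver groups for 274 genes by limma. Of these, 11 lie on chromosomes X or Y, and the Cdx2-Apc libraries stand apart in Xist and Y genes. Differences in sex or tamoxifen between the groups, if present, would not cancel for the other genes either. The count was 9 with a pseudocount of 0.1 FPKM and 4 with a mean of at least 5 FPKM. It was 3 with the smooth muscle covariate and 14 with the columnar covariate. The smooth muscle score sets the Lgr5-Cdx2-Apc libraries apart, so the fit with it cannot tell group from muscle content. The largest log2 values were 7.06 for Xist, 4.56 for Krt71, 4.04 for Il12rb2, 4.03 for Krtap19-4, 4.00 for Krt24, 3.95 for Tchh, 3.92 for Krtap6-5, 3.89 for Krtap15, 3.71 for Krtap19-2 and 3.63 for H2-M2. The lowest were -5.15 for Actg2, -4.34 for Cnn1, -4.23 for Myl9, -4.19 for Acta2, -3.94 for Eif2s3y, -3.80 for Cd177, -3.58 for Car2, -3.42 for Ddx3y, -3.38 for Gpx2 and -3.28 for Ceacam10.

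Skin, hair and skeletal muscle transcripts stood higher than in control in both Lgr5-Cdx2-Apc libraries, where the epidermal keratins Krt5 and Krt14 reached 2790 and 2137 FPKM in replicate 1 and 2881 and 2807 in replicate 2. The skeletal muscle signal also stood in a library with a single driver, Lgr5-Apc replicate 2, with a score of 4.68 against 4.40 and 4.75 and Acta1 at 205 FPKM against 211 and 232. Perianal skin and striated muscle in the dissected tissue are a candidate source. Markers of melanocytes and Langerhans cells (Pmel, Dct, Tyr, Tyrp1, Mlana, Cd207), 0 of which reached 1 FPKM in a control, were higher by a median of 0.66 on the log2 scale (0.21 to 3.90). In both Lgr5-Cdx2-Apc libraries 4 of 6 were higher than in all 10 others, but Tyr only at 0.0335 FPKM in replicate 1 against 0.0287 in Lgr5-Apc replicate 2. In Lgr5-Cdx2-Apc replicate 1, Pmel, at 0.489 FPKM, lay within the control values and Mlana was listed at 0. Cd207 was 16.4 and 20.1 FPKM against 2.47 and 2.64 in Lgr5-Apc replicates 2 and 3 and at most 0.389 in the other 8 libraries. In Lgr5-Apc replicate 2, the melanocyte genes Dct, Tyr, Tyrp1 and Mlana were 0.169, 0.0287, 0.0623 and 0 FPKM. Dct lay within the control values, while Tyr and Tyrp1 were listed at 0 in control and Cdx2-Apc. Values this near 0 cannot show whether the melanocyte genes follow the squamous and skeletal muscle scores there. For the keratins, the combination of both drivers cannot be told apart from sampled tissue, since 2 of the 10 other libraries, Lgr5-Apc replicates 2 and 3, lay at or above the lower squamous score of 7.07, and whether gut epithelium turned to a skin type was not tested.

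Hoxa13, Hoxb13 and Hoxd13, genes of the most posterior body, were low in Lgr5-Apc replicate 4, at 1.33, 0.924 and 0.395 FPKM, and also in Lgr5-Cdx2-Apc, at 0.242, 0.666 and 0.787 FPKM in replicate 2 and 3.29, 10.4 and 4.08 in replicate 1. The other 3 Lgr5-Apc libraries exceeded replicate 4 in these genes by factors of 5.98 to 228, which argues against a common effect of the Lgr5 driver but does not exclude it, since the Lgr5-Cdx2-Apc libraries carry that driver too. The low values there are not alike in tissue, however. The columnar epithelium score was 6.33 and 3.84 in Lgr5-Cdx2-Apc but 8.59 in Lgr5-Apc replicate 4. Tissue from a more anterior part of the gut may account for the pattern: over 18 other Hox genes, the difference from the median of 9 other libraries, those without both drivers, was compared with the paralog number (Spearman's rho = -0.33 across genes, one-sided permutation p = 0.0872, 100000 resamples), which missed the threshold. That test left out 13 genes already seen or in fixed lists and held 2 with a paralog number above 8; over all 31 Hox genes other than Hoxa13, Hoxb13 and Hoxd13, with Hoxa9 at -2.97, Hoxa10 at -2.19, Hoxd12 at -2.15, Hoxb6 at 4.24, Hoxb8 at 4.18 and Hoxb9 at 2.22, rho was -0.47 (one-sided permutation p = 0.00368, 100000 resamples), though genes are not independent replicates. Neither an anterior sample nor an effect of the driver could be excluded, so they cannot be told apart, and a mislabelled sample was not tested.

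Cdx2-Apc stood apart from the other groups in Xist and Y genes, and control replicate 1 had low values of the Y genes. Male mice in Cdx2-Apc and female mice elsewhere are a candidate explanation: the X genes Ddx3x, Eif2s3x and Kdm5c, which escape inactivation, were lower than in control by a median log2 difference of -0.32 (-0.45 to -0.15), 3 of 3 in the direction that 1 X chromosome gives. In control replicate 1, the 4 Y genes stood at 11.4% to 13.4% of their Cdx2-Apc means, a ratio of highest to lowest of 1.17, which is consistent with a share of male RNA in that library. Apc deletion by the Cdx2 driver does not account for the values of these genes, since the Lgr5-Cdx2-Apc libraries, which carry that driver too, had all 4 Y genes listed at 0 and Xist at 215 and 266 FPKM, at least 192 times the highest value in Cdx2-Apc. For genes outside chromosomes X and Y, sex goes together with group in every comparison with Cdx2-Apc and stays open.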

How the results depend on the processing

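The leaving out of a pair of libraries, the columnar covariate, the short RNA removal and the removal of X and Y genes were chosen after seeing the data. Counts below are in the order Lgr5-Apc, Cdx2-Apc and Lgr5-Cdx2-Apc against control (2, 7, 3315 as reported), Lgr5-Cdx2-Apc against Lgr5-Apc and against Cdx2-Apc (1560, 4132), Lgr5-Apc against Cdx2-Apc (6) and the departure from additivity (274). Counts not mentioned stayed within 1.5 times those. Except where stated, the cause was not tested.

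A pseudocount of 0.1 FPKM gave 2 for Cdx2-Apc against control and 9 for additivity, and one of 5 FPKM 1 for Lgr5-Apc against control and 420 for additivity. No filter gave 465 for additivity. A mean of at least 5 FPKM, which tests fewer genes, gave 1, 2, 1925, 502, 2694, 1 and 4. Library quality weights gave 11 for Cdx2-Apc against control, then 6320, 3843, 6925, 56 and 2192. The replicate block gave 0 for Lgr5-Apc against control (2695 at an unadjusted p under 0.05), 2 for Cdx2-Apc against control, 579 for Lgr5-Cdx2-Apc against Lgr5-Apc and 57 for additivity. Fits on the compared groups alone, with fewer samples, gave 1 for Cdx2-Apc against control and 162 for Lgr5-Cdx2-Apc against Lgr5-Apc. The smooth muscle covariate, in which the Lgr5-Cdx2-Apc libraries lie apart from the others, gave 1 for Lgr5-Apc against control, 0 and 0 for Lgr5-Cdx2-Apc against control and against Cdx2-Apc (1390 and 1944 at an unadjusted p under 0.05), 2 against Lgr5-Apc and 3 for additivity. The squamous covariate gave 1492, 789 and 175 for Lgr5-Cdx2-Apc against control, against Cdx2-Apc and additivity. The columnar covariate gave 64, 83, 61 and 14 for the 3 comparisons of Lgr5-Cdx2-Apc and additivity. Without Lgr5-Apc replicate 4 and control replicate 1 the counts were 21, 20, 977 (against Lgr5-Apc), 12 and 126. Short RNA removal gave 1 for Lgr5-Apc against control. Removal of X and Y genes left 1 for Cdx2-Apc against control and 0 for Lgr5-Apc against Cdx2-Apc (1737 at an unadjusted p under 0.05), as those genes are the ones removed. Median-of-ratios and quantile scaling, robust moderation and a log2 change of at least 1 kept all 7 counts within 1.5 times.

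Leaving out 1 library at a time, with a lone remaining library assumed to vary like the others, gave 1 to 32, 6 to 22, 428 to 4686, 284 to 4463, 506 to 5337, 6 to 14 and 67 to 2386 genes. List calls by camera (16, 6, 18, 21, 18, 18 and 24) ran from 5 to 22, 5 to 15, 16 to 20, 17 to 22, 18 to 20, 11 to 19 and 19 to 25. The low of 5 for Lgr5-Apc against control came without control replicate 3, with 10 without replicate 2, the 15 for Cdx2-Apc against control without control replicate 1, and the 11 for Lgr5-Apc against Cdx2-Apc without Cdx2-Apc replicate 1. An estimated correlation gave 0 list calls in each comparison, with 0, 1, 3, 4, 2, 1 and 2 lists at an unadjusted p under 0.05. By fry there were 0 list calls for Lgr5-Apc against control (0 at an unadjusted p under 0.05), 1 for Cdx2-Apc against control, 9 for Lgr5-Cdx2-Apc against control, 11 against Lgr5-Apc, 1 for Lgr5-Apc against Cdx2-Apc and 7 for additivity, and fry kept 36 of the 121 camera calls.

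For named genes over all alternatives, 5368 values kept their direction and side of the threshold, 1056 lost the call, 27 gained it and 9 reversed. The reversed values against control were, with the smooth muscle covariate, 0.17 for B3gnt7, 0.58 for Hoxd10, 0.66 for Sval1 and 0.00 for Sycn, and with the columnar covariate 0.26 for Cdx1, 0.04 for Creb3l1, 0.10 for St6galnac6 and 0.09 for Tff3. Cdx1 is itself a member of the columnar score, so its value under that covariate is not informative. Against Cdx2-Apc, Tff3 was 0.33 with the columnar covariate. Count-based tests and a test on recovered reads were not run, since the values are FPKM. The fit on the compared groups alone does not apply to additivity. Depth in reads is unknown, so what depth limits cannot be stated.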

Other observations

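The tests in this part, other than that of the mast cell list, were chosen after the results were seen.

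Gamma delta T cell receptor segments stood out with both drivers. Trdv4, the variable segment of the skin-type delta chain, was 22.1 and 24.2 FPKM in Lgr5-Cdx2-Apc and at most 1.10 in the other libraries, and Tcrg-V5, a gamma chain variable segment, was 12 and 7.32 FPKM against at most 1.20. Trdc was 3.49 and 4.61 FPKM against at most 0.205. In the mast cell list, 2 of 4 genes rose against control, over all genes and adjusted over the list alone, without a call for the list (camera adjusted p = 0.0719; adjusted p = 0.629 with an estimated correlation): the mast cell proteases Mcpt4 by 2.50 ± 0.35 and Tpsb2 by 1.41 ± 0.25 (SE), while Cma1 at 1.09 ± 0.54 did not pass.

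In Lgr5-Apc replicate 4, Hoxb6 was 61.3, the mucin Muc2 7725 and the antimicrobial lectin Reg3b 504 FPKM, each the highest of all 12 libraries. Eno1b was 15.5, 9.49 and 14 FPKM in the controls, 9.16 in Cdx2-Apc replicate 1, 0.919 and 0.397 in Cdx2-Apc replicates 2 and 3 and at most 0.144 in the other 6 libraries. Ighv1-85 was 0.972, 1.71 and 0.722 FPKM in Cdx2-Apc and listed at 0 in Lgr5-Apc and Lgr5-Cdx2-Apc.

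A hypothesis was that gene groups called higher with both drivers follow the amount of squamous epithelium, tested for 4 groups over the 10 other libraries with permutation tests of 100000 resamples, two-sided and Benjamini-Hochberg adjusted over the 4 relations. The 6 Wnt targets that rose (Axin2, Tcf7, Apcdd1, Wif1, Tnfrsf19, Lgr6) followed the squamous score with Pearson's r = 0.84 (p = 0.00072, adjusted 0.00288) and Spearman's rho = 0.70 (p = 0.0303, adjusted 0.121), and r was 0.77 without Lgr5-Apc replicates 2 and 3, the libraries farthest from the median. Their rise may therefore reflect squamous tissue, although the rank test missed the threshold after adjustment. The 5 tuft cell genes had r = 0.70 (p = 0.0166, adjusted 0.0332) and rho = 0.43 (p = 0.216, adjusted 0.432), but r = -0.10 without the same libraries, so that relation rests on them. For the 10 T and NK cell genes r was 0.13 (p = 0.716, adjusted 0.879), with rho = 0.04 (p = 0.917, adjusted 0.917), and for the 5 MHC class II genes r was 0.06 (p = 0.879, adjusted 0.879), with rho = -0.05 (p = 0.892, adjusted 0.917); without the same libraries r was -0.58 and -0.28. More squamous epithelium did not account for the rise of the T and NK cell list: Lgr5-Apc replicates 2 and 3, whose squamous scores of 9.17 and 8.39 reach the 7.07 of Lgr5-Cdx2-Apc replicate 1, held at most 10.2% of the rise of its 13 tested members over control. The gap of 1.35 on the log2 scale to the lower Lgr5-Cdx2-Apc library was wider than the range of 0.32 over the 10 other libraries. The same libraries held at most 9.57% of the rise of the 8 MHC class II genes, 13.4% of that of the 13 tuft cell genes and 54.3% of that of the 20 Wnt targets. There the gaps of 1.84, 0.74 and 0.34 lay inside the ranges of 2.05, 1.23 and 0.64, so squamous tissue stays open for these lists. The squamous score does not separate skin from other squamous epithelium, so immune cells that come with skin stay open. No batches are given in the labels, and within single groups the libraries are too few for a correlation.

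Other splits of the samples were counted for comparisons with at least 3 libraries per group. For Lgr5-Apc against control, 5 of the 35 splits gave at least the real 2 genes, so chance could not be excluded. The highest other split gave 780 genes, with control replicates 2 and 3 and Lgr5-Apc replicates 1 and 4 against control replicate 1 and Lgr5-Apc replicates 2 and 3, which points to a structure of the samples that follows the squamous score. For Lgr5-Apc against Cdx2-Apc, 2 of 35 splits (5.71%) gave at least the real 6 genes, with 8 in the highest other, so chance could not be excluded from the count of splits. That other split joins Lgr5-Apc replicate 1 to the 3 Cdx2-Apc libraries and keeps most of the difference in sex-linked genes, whose values do not overlap, with Xist at 61.1 to 163 FPKM in Lgr5-Apc and 0.702 to 1.12 in Cdx2-Apc. For Cdx2-Apc against control there are 10 splits, too few for a share under 0.05; 2 gave at least the real 7 genes, and the highest other gave 29.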
